A study of Mus musculus with 2 samples.

How the data were processed

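The series measured RNA in single medullary thymic epithelial cells (mTEC) of C57BL/6 mice, sorted as the low-MHC fraction (mTEClo) without Pdpn and CD104 on the surface. Per the labels, thymi were digested, cells with CD45 were removed with magnets, and each of 7 samples was stained with its own DNA-tagged antibody against H2-Kb, a hash tag that marks the sample of origin. All 7 samples then went through 1 run of 10x Genomics droplets with 3' v3.1 chemistry. The groups came from the labels that join each hash tag to a sample. 3 samples, named Hnf4ctrl, carried Foxn1-cre, 1 floxed and 1 normal copy of Hnf4a, and 1 normal and 1 null copy of Hnf4g. 4 samples, named Hnf4dTEC, carried Foxn1-cre, floxed copies alone of Hnf4a, and null copies alone of Hnf4g. Foxn1-cre recombines floxed genes in thymic epithelial cells. The labels do not say whether each sample was a separate animal, so p-values here measure only the spread between these samples. A second library of the series held the hash tags alone; it belongs to no group and served to check the assignment of cells.

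The deposited matrix held the UMI count of each gene and each antibody tag per droplet barcode, as whole numbers, with 18089 barcodes, 55487 genes and 15 antibody features. A UMI is a tag that marks 1 captured RNA molecule. The submitters' processing notes name Cell Ranger 6.1.0, Seurat 4.0.2 and the mouse build mm10, while the header of the matrix names Cell Ranger 7.0.0. The deposited cell table, made by the authors, gave 9185 barcodes a sample and 1 of 15 cell classes, and the other 8904 barcodes had no entry. Gene positions came from GENCODE mouse release 21, in which 54349 of the gene identifiers were found with the same version. Genes were kept apart by identifier, since 234 of them share a symbol with another gene.

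All 9185 annotated cells were kept. A filter of at least 500 genes and at most 15% mitochondrial UMIs removed 0 cells, since the annotated cells had at least 1254 genes and at most 7.50% mitochondrial UMIs. Another filter of 1000 genes and 10% also removed 0 cells and so tested nothing. In 45 annotated cells the most abundant hash tag belonged to another sample. Doublets were scored on 13696 barcodes with Scrublet, as built into scanpy 1.11.5, which marked 235 annotated cells (2.56%). Of the barcodes without annotation, 2558 had 2 strong hash tags, the second with at least 150 UMIs and 20% of hash UMIs. Scrublet marked 631 of them (24.7%). If most of these barcodes are doublets, it missed most doublets of this kind. Expression of each pair of samples correlated with a Spearman rho between 0.964 and 0.986 across genes, and no sample was a copy of another, with a chi-square per degree of freedom of at least 5.58.

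UMI counts were summed per sample, over all cells or within a class, and tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) after its filter for low counts and TMM normalisation. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05 on the adjusted p, and all tests were two-sided. CPM means counts scaled to 1000000 per sample after TMM normalisation, or to 1000000 per sample and class without TMM where a list was summed, and log2 fold changes are mutant over control. Within a class, samples with at least 10 cells were used and at least 3 samples per genotype were required, which left 11 classes. The main tests, alternatives, lists and rule for naming genes were chosen before the data were examined. Shares of cells per class were tested with edgeR on cell counts, with all cells of a sample as its library size, and with a two-sided exact permutation of the 7 samples. Those samples make 35 splits, so the smallest p is 0.0286; a comparison of 3 against 3 samples makes 20 ordered splits, with a smallest p of 0.1.

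The plan took classes from Leiden clusters made without the gut and liver genes, because the knockout was likely to change those genes. The authors' own classes were used in their place once the deposited cell table proved to hold them, and the planned clusters became an alternative whose values are given. That clustering used 2000 variable genes, 30 principal components, 20 neighbours, resolution 1, leidenalg 0.10.2 and random seed 0, with 153 genes left out. It was also run at resolutions 0.5 and 2, and with the gut and liver genes kept.

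A set of 8 gene lists was fixed: gut epithelium, liver, lipoprotein and lipid absorption, gut and liver transcription factors, MHC class II, interferon response, dissociation stress and thymic epithelium. Another 20 lists held markers of Aire-stage mTEC, immature mTEC, proliferating cells, cortical thymic epithelium, tuft, microfold, neuroendocrine, entero-hepato, secretory, ciliated, muscle, keratinocyte, lung, ionocyte, pancreatic, parathyroid, thymocyte, myeloid or B, fibroblast and endothelial cells. Lists with at least 3 tested members went into camera with a preset correlation between genes, with camera at an estimated correlation and fry beside it. Camera asks whether a list moved more than other genes, and fry asks whether its genes moved, on balance, in 1 direction. Some genes are on several lists. For the test of lists by class, the CPM of a list's members was summed per sample and class and compared by exact permutation, with adjustment over the classes of each list. Camera with an estimated correlation was also run on the genes of each class, adjusted over the lists of that class, which was not planned.

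Genes were named by rule. Hnf4a, Hnf4g and Foxn1 were always named. In all cells, the rule took the 10 lowest and 10 highest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the genotypes. Each list gave up to 4 members past the threshold, or up to 2 of the highest mean CPM. Each class gave the 5 lowest and 5 highest fold changes past the threshold with a mean log2 CPM of at least 5.

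Alternatives were the Wald test of DESeq2 1.42.0, DESeq2 size factors, no filter for low counts, replicate number as a block, cells that Scrublet marked left out, each sample thinned to 801 cells, 13 classes weighted to 1 mix and tested in limma with 1 CPM added, and each sample left out in turn. The 13 weighted classes were those with cells in every sample, which left out Entero-hepato and Ionocyte cells. Within classes a minimum of 20 cells was also tried. Alternatives added after seeing the data were a filter of 2000 genes and 5% mitochondrial UMIs, which left out 591 cells, Entero-hepato cells left out, Tuft cells left out, cells with the top hash tag of another sample left out, and Reg3g left out of the gut epithelium list in the sums by class. Tables and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

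The tests were checked on simulated counts with the same samples and depths. In the simulations of genes and lists each gene was drawn independently, without correlated genes or a class mix that differs between samples. Among the real lists the estimated correlation reached 0.97, so the rates of false calls below hold for independent genes only. In all cells, edgeR called 31.3% of genes changed 1.5-fold, 58.2% of genes changed 2-fold and 87.9% of genes changed 4-fold, and 5 of 20937 unchanged genes. In Tuft cells, the deepest class, those shares were 67.2%, 82.1% and 97.0%, and in Microfold cells, with the fewest genes tested, 2.99%, 25.4% and 86.4%. A list of 50 genes lowered 1.5-fold was called with preset and estimated correlation in all cells and in each class, and none of 20 unchanged lists was. The test of shares was simulated over 40 rounds in 4 settings, of which all but the first were designed after the first had been seen, because tripling large classes lowers the share of every other class. With any 3 classes tripled it called 65 of 120 (54.2%), and 109 of 480 other classes, whose shares had moved. With 3 classes of 1 to 10% tripled it called 90 of 120 (75%), and 21 of 480 others. With 3 classes of 1 to 6% tripled at the expense of Tuft cells it called 111 of 120 (92.5%), and 5 of 440 classes that had kept their share (1.14%). With no class changed it called 3 of 600 (0.5%). The simulated noise was independent between classes and milder than in some real ones, as in Aire-expressing cells, at 8.01% ± 4.83 in control samples. Other splits of the real samples called up to 4 shares, so these rates do not carry over to the real data.

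Total UMIs per sample ran from 10127838 to 25821970. Samples of 1 class ran from 253250 to 10926000 UMIs. Intervals and limits from counts cover counting error only.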

Results

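The data were UMI counts of 9185 sorted mTEClo cells from 7 hash-tagged samples, 3295 cells from 3 control samples and 5890 cells from 4 mutant samples. mTEC include mimetic cells, which take on gene programs of peripheral tissues such as gut, liver, skin and muscle. The control samples 1, 2 and 3 held 801, 915 and 1579 cells with 10127838, 12284963 and 25821970 UMIs. The mutant samples 1, 2, 3 and 4 held 1652, 1377, 1488 and 1373 cells with 23501741, 19321440, 20637920 and 21623750 UMIs. Median UMIs per cell were 11528, 12022 and 15053 in the control samples and 12814.5, 12679, 12535 and 14025 in the mutant samples. Samples of both genotypes differed in their mix of classes, since Tuft cells made up 31.1% of control sample 3 and 55.6% of control sample 1, against 36.7% of mutant sample 4 and 52.7% of mutant sample 2.

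The first comparison asked whether the transcripts of the targeted genes were lower in the mutant samples. Hnf4a and Hnf4g encode nuclear receptors of the same family that bind DNA and drive genes of liver and gut epithelium. Hnf4g fell from 118 ± 3.94 CPM (SD, n = 3) to 83.4 ± 4.99 CPM (SD, n = 4). Its log2 fold change was -0.50 (SE 0.06, edgeR adjusted p = 0.0384). It was not lower in every class, with 201 and 250 CPM in Aire-adjacent and 24.6 and 46.7 CPM in Immature cells, where it did not pass. Over all cells Hnf4a was near the floor of detection, with 2.56 ± 0.779 CPM in control samples and 1.56 ± 0.656 CPM in mutant samples. Neuroendocrine cells had more of it, at 19.6 ± 1.89 and 14.7 ± 7.60 CPM (64 and 88 UMIs). Hnf4g was at 221 and 223 CPM in those cells. Over all cells Hnf4a did not pass the test (log2 fold change -0.72, SE 0.40, edgeR adjusted p = 0.874). Foxn1, the master transcription factor of thymic epithelium and the driver of the cre, did not pass either, at 30.2 ± 4.49 and 25.9 ± 2.65 CPM (log2 fold change -0.23, edgeR adjusted p = 0.854). Hnf4a (ENSMUSG00000017950.16) lies on the plus strand of chromosome 2 from 163506808 to 163572910 in mm10, and Hnf4g (ENSMUSG00000017688.14) on the plus strand of chromosome 3 from 3508030 to 3658052. The assay reads the 3' end of transcripts, which may lie outside the deleted part, so these levels neither prove nor rule out the deletion. The Hnf4g call was lost when any 1 of the 7 samples was left out (edgeR adjusted p between 0.0720 and 0.184). Its log2 fold change was -0.33 without Entero-hepato cells (edgeR adjusted p = 0.406) and -0.19 with classes weighted to 1 mix. The weighting also left out Entero-hepato cells. Over all alternatives the adjusted p of Hnf4g ranged from 1.12e-07 with DESeq2 to 0.406.

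The next comparison asked which genes changed in mTEClo as a whole. Of 21187 genes tested, 38 were lower and 1 was higher in the mutant samples, and the lower genes included several of intestine and liver. Apoc3, an apolipoprotein of triglyceride-rich particles made by liver and gut, fell from 30.05 ± 17.6 CPM (SD, n = 3) to 1.47 ± 0.504 CPM (SD, n = 4). Its log2 fold change was -4.38 (SE 0.49, edgeR adjusted p = 0.0374). Anks4b, a scaffold protein that helps assemble the brush border of enterocytes, fell from 17.0 ± 1.09 to 4.28 ± 0.370 CPM (log2 fold change -1.99, SE 0.11, edgeR adjusted p = 0.00197). Serpinb1a, an inhibitor of neutrophil proteases, was the most abundant of the named genes that fell, from 359.8 ± 40.5 to 134.8 ± 17.3 CPM (log2 fold change -1.42, SE 0.12, edgeR adjusted p = 0.00991). Ddc, the decarboxylase that makes serotonin and dopamine, fell to 4.43 ± 0.804 from 17.8 ± 1.99 CPM. Mep1a, a metalloprotease of the brush border, fell by 1.79 on the log2 scale, to 5.11 ± 1.22 from 17.6 ± 4.14 CPM. Vil1, which bundles actin in microvilli, fell by 1.06, and Krt20, a keratin of differentiated gut epithelium, fell by 1.13. Trf, the iron carrier of plasma, which the liver makes, fell by 1.42, and the chemokine Ccl6 fell by 2.06. The other named genes that fell were Rgs4, a regulator of G protein signalling (-1.31), Nostrin, an adaptor that binds nitric oxide synthase (-1.27), Ptchd4 (-1.21) and Scg5, a chaperone of prohormone processing in neuroendocrine cells (-0.49). Bex4 was the single higher gene, at 53.3 ± 6.12 against 29.5 ± 1.91 CPM (log2 fold change 0.85, SE 0.10, edgeR adjusted p = 0.0384).

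Adjusted p-values in edgeR for these lower genes ranged from 0.00197 for Anks4b to 0.0470 for Ccl6. Anks4b lies on the plus strand of chromosome 7 from 120173858 to 120185586 and Apoc3 on the minus strand of chromosome 9 from 46232933 to 46235636. The count of 39 genes rested on all samples: without control samples 1, 2 or 3 edgeR called 31, 2 and 11 genes, and without mutant samples 1, 2, 3 or 4 it called 2, 4, 5 and 7. Anks4b passed each time, and each other named gene lost its call without at least 1 of the samples. Without Entero-hepato cells 9 genes were called, all of them among the 39. Ddc, Anks4b, Serpinb1a, Nostrin and Ptchd4 still passed, while Apoc3 (-2.50) and Vil1 (-0.93) did not. With classes weighted to 1 mix, which also left out Entero-hepato cells, limma called 59 genes, of which 24 were among the 39. Without Tuft cells edgeR called 46, of which 23 were among the 39. Without Tuft cells the log2 fold change of Bex4 was -0.42, in the other direction.

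**Figure D1:**
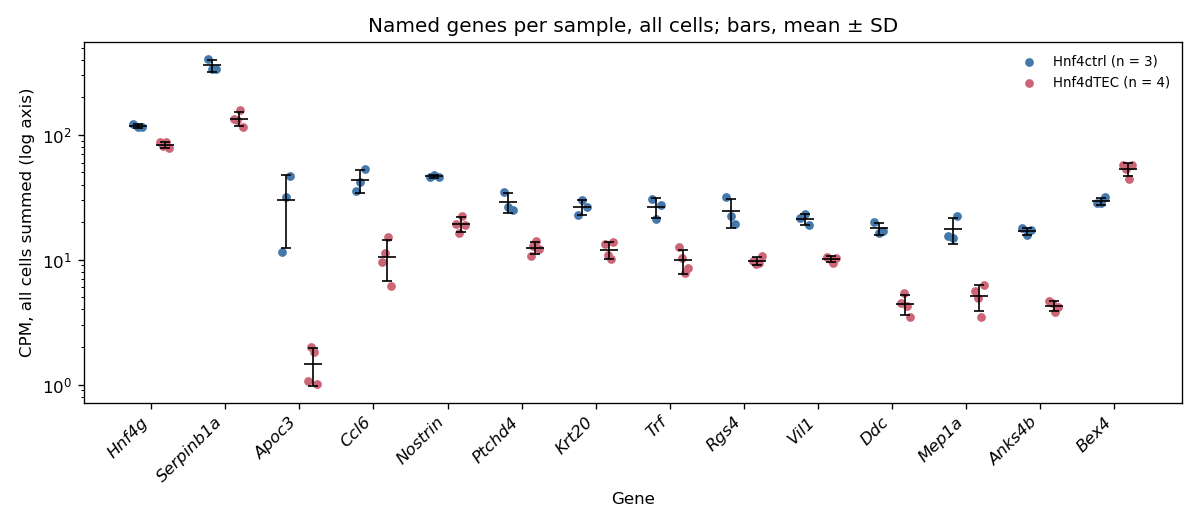
Expression of the 14 named genes in all mTEClo cells of each sample, in CPM on a log axis; dots are samples (3 control, 4 mutant) and bars give the mean with its SD. Apoc3 spanned 11.6 to 46.6 CPM in control samples and 1.01 to 1.99 CPM in mutant samples.

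Lists of genes asked whether gut and liver programs moved together. The gut epithelium list was lower, with a median log2 fold change of -0.67 over 45 tested members of 50 (camera adjusted p = 2.48e-37; adjusted p = 0.0414 with an estimated correlation). Of those members 3 fell over all genes tested and 21 fell adjusted over the list alone, with 0 higher, and Vil1, Mep1a and Krt20 were the 3. The entero-hepato markers were lower too, with a median of -1.04 over 18 members (camera adjusted p = 5.09e-44, or 0.0242 with an estimated correlation). Of those markers 3 were lower over all genes tested, Hnf4g, Apoc3 and Vil1, and 14 adjusted over the list alone. Hnf4g is itself a targeted gene, so its fall adds no separate support. Apoc3 is also on the liver list and Vil1 on the gut epithelium list. The liver list had a median of -0.47 over 48 members (camera adjusted p = 2.38e-08), with 2 lower over all genes, Apoc3 and Trf, and 9 adjusted over the list alone. Its call was lost in camera with an estimated correlation (adjusted p = 0.352). With 1 sample left out the liver median ran from -0.51 to -0.049. An absolute liver median as large came from 7 of 35 splits of the samples, the real one among them. The list of lipoprotein and lipid absorption genes had a median of -0.65 over 20 members (camera adjusted p = 3.71e-12), with Apoc3 alone lower over all genes and 8 adjusted over the list alone. The lipoprotein call was also lost in camera with an estimated correlation (adjusted p = 0.0925). Its median ran from -0.79 to -0.31 with 1 sample left out, and 4 of 35 splits gave an absolute median as large. The gut and liver transcription factors gave no call, with a median of -0.06 over 23 members, 0 past the threshold in edgeR over all genes or the list alone (camera adjusted p = 0.288; fry adjusted p = 0.0943).

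Of the other marker lists, 4 passed camera with the preset correlation and none of these passed with an estimated one. The microfold markers had a median of -0.47 over 11 members (camera adjusted p = 8.84e-18; adjusted p = 0.0839 with an estimated correlation), with Ccl6 lower over all genes and 5 adjusted over the list alone. Cortical thymic epithelium markers had a median of -0.37 over 8 members (camera adjusted p = 0.00222; adjusted p = 0.296 with an estimated correlation) and 0 members past the threshold. Neuroendocrine markers had a median of -0.16 over 13 members (camera adjusted p = 0.00222; adjusted p = 0.487 with an estimated correlation), with Scg5 as the 1 member lower. Muscle markers had a median of 0.39 over 13 members (camera adjusted p = 0.0232, or 0.750 with an estimated correlation). That median ran from 0.043 to 0.85 with 1 sample left out, and 20 of 35 splits of the samples gave an absolute median as large. Of 27 lists tested, the other 19 did not pass, with medians between -0.17 and 0.15, camera adjusted p of at least 0.183 and 0 members past the threshold over all genes. Those were, beside the transcription factors, MHC class II, interferon response, dissociation stress, thymic epithelium, and the markers of Aire-stage mTEC, immature mTEC and proliferating, tuft, secretory, ciliated, keratinocyte, lung, ionocyte, pancreatic, thymocyte, myeloid or B, fibroblast and endothelial cells. Adjusted over the list alone, secretory markers had 1 member higher, lung markers 2 higher and 1 lower, and fibroblast markers 1 lower. For the ciliated, lung and thymocyte markers the median was negative while camera gave an upward direction, and the mean was 0.26 for the thymocyte markers. The parathyroid list had too few tested members for a list test. Estimated correlation and fry each left 2 lists, those of gut epithelium and entero-hepato cells, and without Entero-hepato cells the gut epithelium list still passed (median -0.67, adjusted p = 0.00725 with an estimated correlation).

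The next comparison asked whether any cell class was lost or gained. The Entero-hepato class, mTEC with genes of gut and liver, was nearly absent from the mutant samples, with 3 of 5890 cells against 82 of 3295 cells in the control samples. Its mean share was 2.19% ± 1.25 (SD, n = 3) in control and 0.0484% ± 0.0593 (SD, n = 4) in mutant samples, a log2 fold change of -5.25 (SE 0.68, edgeR adjusted p = 6.16e-05). The ratio of the pooled shares was 48.9, with an exact 95% counting interval of 16.1 to 241.8. Control samples 1, 2 and 3 held 8, 19 and 55 such cells, mutant samples 1 and 2 held 2 and 1, and mutant samples 3 and 4 held 0, which allows shares of up to 0.202% and 0.218% with 3 cells taken as the limit of a count of 0. Each mutant sample lay below each control sample, and the exact permutation p of 0.0286 was the smallest that 35 splits can give (adjusted p = 0.286 over the classes).

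No other class passed in edgeR. Microfold cells, which in the gut take up antigen, were at 2.36% ± 0.335 and 1.28% ± 0.520 (log2 fold change -0.86, edgeR adjusted p = 0.304, exact permutation p = 0.0571). Secretory cells were at 4.11% ± 0.843 and 5.99% ± 1.20 (0.54, edgeR adjusted p = 0.462), and Tuft cells, the most abundant class, at 44.0% ± 12.3 and 46.8% ± 7.12 (0.09, edgeR adjusted p = 0.971). For each of the other classes the edgeR adjusted p was at least 0.706. The loss of Entero-hepato cells held in edgeR without any 1 sample (log2 fold change -6.08 to -4.69). It depended on the authors' classes. Leiden clusters made without gut and liver genes, which had been the planned classes, placed 76 of the cells called Entero-hepato in a cluster of 578 cells with 367 Aire-adjacent cells, and no cluster share passed. That cluster was at 8.31% ± 3.03 and 4.73% ± 0.381 (log2 fold change -0.82, SE 0.27, edgeR adjusted p = 0.111, exact permutation p = 0.0286).

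**Figure D2:**
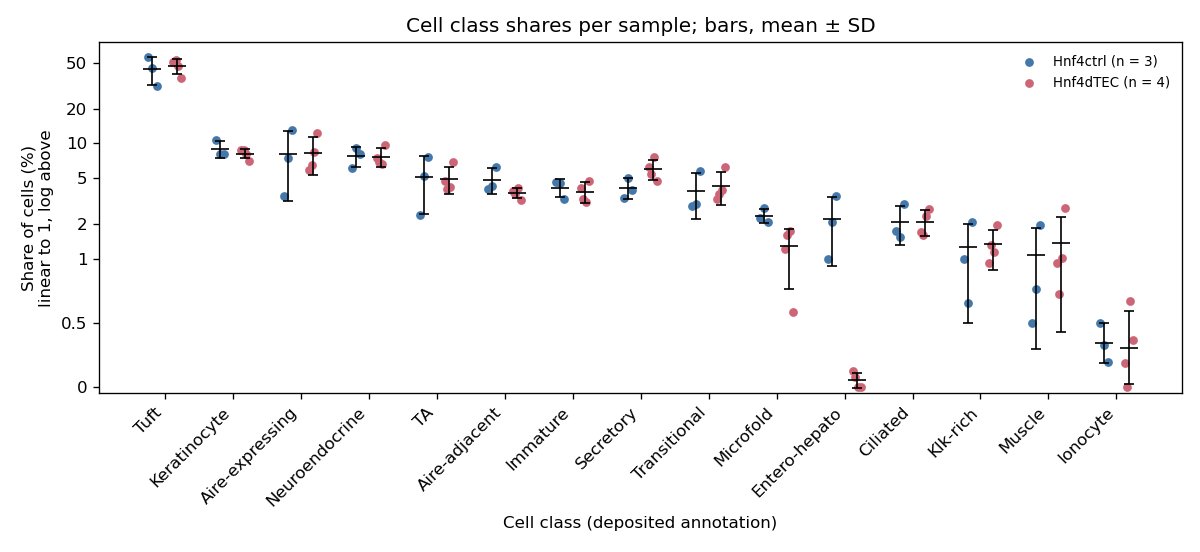
Share of annotated cells in each class per sample, in percent, on an axis that is linear to 1 and logarithmic above; dots are samples (3 control, 4 mutant) and bars give the mean with its SD. Entero-hepato cells made up 0.999 to 3.48% of control samples and 0 to 0.121% of mutant samples.

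Within classes, the question was whether expression changed in cells other than Entero-hepato cells. Microfold cells had 109 genes lower and 32 higher of 4656 tested, and Neuroendocrine cells had 38 lower and 6 higher of 11297. Control samples 1, 2 and 3 held 18, 25 and 33 Microfold cells, and mutant samples 1, 2 and 3 held 20, 22 and 26. Mutant sample 4, with 8 Microfold cells, was not used for that class. Tuft cells had 10 lower and 3 higher of 14760, Keratinocyte cells 7 lower and 2 higher of 11267, and Secretory cells 3 lower of 9556. In Microfold cells Trf gave 162 UMIs in control and 1 in mutant samples, a ratio of 131 with an exact 95% counting interval of 23.2 to 5203 (edgeR adjusted p = 0.000499). Apoc3 gave 168 and 2 UMIs, a ratio of 67.9 with an interval of 18.5 to 565 (edgeR adjusted p = 0.00631). Trdn, a protein of muscle calcium release (205 and 5 UMIs), Prickle2, of planar cell polarity (145 and 4 UMIs), and Far2, which makes fatty alcohols (188 and 6 UMIs), also fell in Microfold cells. The genes that rose most there were the organic anion transporter Slco1a5 (2.88), 4930434J06Rik (2.84), the skin gene Sbsn (2.77), the lipoxygenase Alox15 (2.76) and the GABA receptor subunit Gabrp (2.65). In that order they had 8, 31, 23, 8 and 7 UMIs in control samples and 52, 175, 129, 47 and 39 in mutant samples.

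In Neuroendocrine cells Hopx, a homeodomain cofactor, fell from 119 ± 4.94 CPM (SD, n = 3) to 16.5 ± 4.35 CPM (SD, n = 4), a log2 fold change of -2.86 (edgeR adjusted p = 4.95e-05). The trefoil peptide Tff3 (-2.98), the microfold receptor Gp2 (-2.49), Ddc (-2.27) and Calml4, a calmodulin-like protein of the brush border (-2.26), fell there too. Pappa2 (1.70), Hs3st5 (1.04), the cell cycle inhibitor Cdkn1a (0.90), Cntnap2 (0.87) and Alox12e (0.78) rose. In Keratinocyte cells Spink1, a trypsin inhibitor, fell from 393 ± 193 to 27.7 ± 5.16 CPM (-3.84, edgeR adjusted p = 0.00187). The small GTPase Rhoc (-2.07), Immp2l (-1.31) and the cystatin Cst6 (7116 and 3557 CPM) fell, while the growth factor Igf1 (1.01) and Eya1 (0.78) rose. In Secretory cells Lgals4, a galectin of gut epithelium, gave 299 UMIs in control and 17 in mutant samples (-5.34, edgeR adjusted p = 0.0203). The chemokine Cxcl9 fell from 138 ± 28.8 to 13.4 ± 10.4 CPM (-3.39, edgeR adjusted p = 0.0203), and the growth factor Bmp2 fell by 2.03; Bmp2 was outside the naming rule and chosen after its values were seen. In Tuft cells Pcsk5, a convertase (-1.10), Rhoc (-0.84), Calml4 (-0.82), Myo15b (-0.74) and Efcab5 (-0.68) were lower and the netrin receptor Dcc (0.56) was higher.

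In 6 classes edgeR called 0 genes. At an unadjusted p under 0.05 there were 451 genes in Aire-adjacent, 666 in Aire-expressing, 255 in Ciliated, 275 in Immature, 411 in TA and 466 in Transitional cells, and DESeq2 called 25, 49, 0, 0, 1 and 1. Without the filter for low counts edgeR called 279, 0, 164, 54, 192 and 115 in the same order. Whether the classes differed in their changes was not tested gene by gene. The counts moved by over 1.5 times with single samples. Without control samples 1, 2 and 3 edgeR called 76, 68 and 75 genes in Microfold and 6, 5 and 52 in Tuft cells; without control samples 1 and 2 it called 26 and 13 in Neuroendocrine cells; without control samples 1 and 3 it called 4 and 4 in Keratinocyte and 6 and 1 in Secretory cells. Without mutant samples 1 and 2 it called 28 and 73 in Microfold and 7 and 5 in Tuft cells, without mutant samples 1, 2 and 3 it called 10, 22 and 26 in Neuroendocrine cells, without mutant samples 1, 2, 3 and 4 it called 3, 2, 3 and 18 in Keratinocyte cells, and without mutant samples 1, 3 and 4 it called 5, 0 and 1 in Secretory cells. Aire-adjacent cells, with 0 in the full data, had 2, 1 and 9 without control samples 1, 2 and 3, Immature cells 2 and 2 without control samples 2 and 3, Transitional cells 2 without control sample 3 and 1 without mutant sample 1, and TA cells 1 without mutant sample 3. Trf, Apoc3, Trdn, Prickle2 and Far2 in Microfold, Hopx, Ddc and Calml4 in Neuroendocrine, Spink1 and Rhoc in Keratinocyte, and Rhoc and Calml4 in Tuft cells kept their calls without any 1 sample, and each other gene named by the rule within a class lost its call at least once.

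The last comparison asked in which classes the gut and liver lists moved, by the summed CPM of each list. For the gut epithelium list, all 4 mutant samples lay below all 3 control samples in Aire-adjacent cells (3248 ± 1961 and 744 ± 142 CPM, log2 difference -1.88), Secretory cells (16570.0 ± 5424 and 9555 ± 1719 CPM, -0.76) and Tuft cells (493 ± 55.5 and 346 ± 15.7 CPM, -0.50). Each of those had an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.105 over the classes. None passed this test, which can pass only when most classes have the smallest p. In Microfold cells the lipoprotein list was at 1933 ± 120 CPM (SD, n = 3) in control and 201 ± 110 CPM (SD, n = 3) in mutant samples, a log2 difference of -3.40, and the liver list was at 561.5 ± 206 and 70.0 ± 20.3 CPM, a difference of -2.98. The gut epithelium list in Microfold cells was at 11037 ± 2933 and 3908 ± 454 CPM (-1.47). With 3 samples against 3 the exact permutation p could not go below 0.1, the value that each of those had. Keratinocyte cells (-1.13, exact p = 0.0857) and Neuroendocrine cells (-1.16, exact p = 0.114) had log2 differences below 0 for the gut epithelium list as well. Reg3g, an antibacterial lectin, made up much of these sums, with 2563 and 253 CPM in Aire-adjacent and 6969 and 2245 CPM in Microfold cells. Without Reg3g the log2 difference was -0.49 in Aire-adjacent, -0.66 in Secretory, -0.35 in Tuft, -0.63 in Keratinocyte, -0.59 in Neuroendocrine and -1.27 in Microfold cells. Each of the first 5 then had an exact permutation p of 0.0286 (adjusted p = 0.0629). For the gut and liver transcription factors no class had an adjusted p under 0.629 in the exact test. No difference between a class and Tuft cells passed after adjustment in the exact test, where 2 of 40 had an unadjusted p under 0.05.

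A list test on the genes of each class was looked at beside the planned test. In camera with an estimated correlation, the gut epithelium list was lower in Tuft (median log2 fold change -0.39 over 16 members, adjusted p = 0.00989), Keratinocyte (-0.81 over 20, 0.0120) and Microfold cells (-2.47 over 11, 0.0178). It was also lower in Aire-adjacent (-0.60 over 11, 0.0272) and Neuroendocrine cells (-0.41 over 20, 0.0279), and it did not pass in Secretory cells (-0.69 over 12, 0.190). The lipoprotein list passed in Microfold cells (adjusted p = 0.0178) and the liver list in Neuroendocrine cells (0.0365). The entero-hepato markers were lower too in Aire-adjacent (-1.04 over 6, adjusted p = 0.0272), Keratinocyte (-1.59 over 7, 0.0245), Microfold (-3.26 over 9, 0.0178), Neuroendocrine (-0.51 over 10, 0.0279) and Tuft cells (-0.56 over 10, 0.00989). Beside these, secretory markers passed in Neuroendocrine (-0.75 over 6, 0.0279) and cortical thymic epithelium markers in Transitional cells (-1.08 over 6, 0.0169), both lower. Other splits of the samples were not counted for these further lists. In Aire-adjacent cells, which shared a Leiden cluster with 76 Entero-hepato cells, it was not tested whether Entero-hepato RNA or cells lay behind the lower lists.

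**Figure D3:**
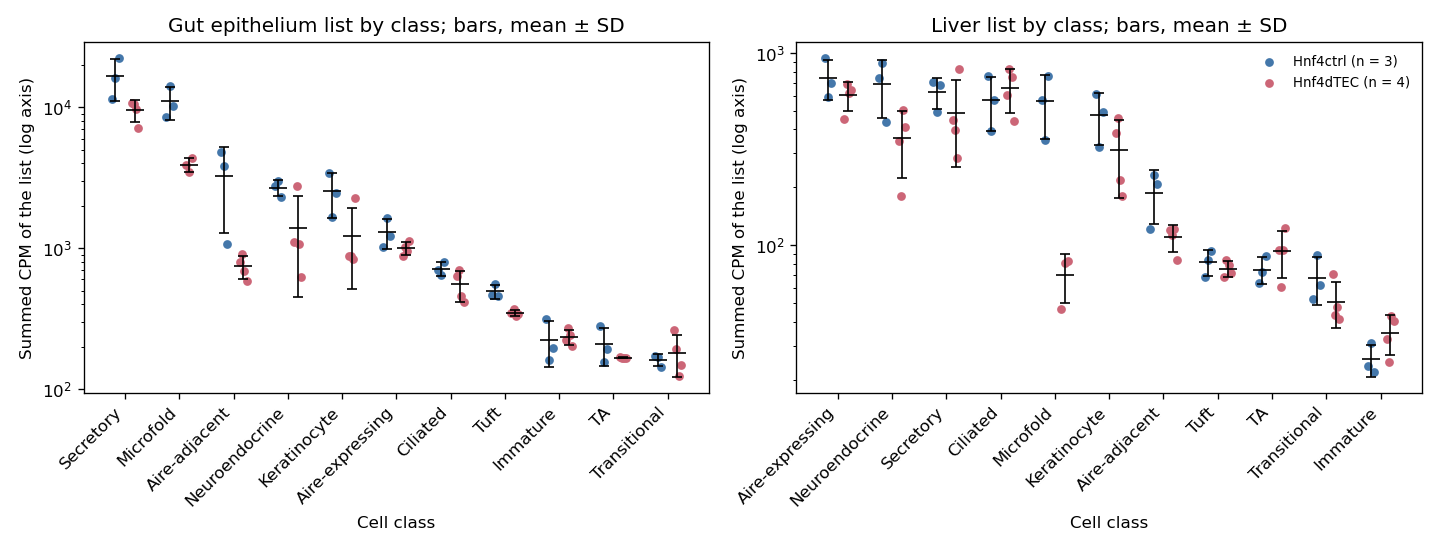
Summed CPM of the gut epithelium and liver lists per sample in each class, on a log axis; dots are samples (3 control, 4 mutant, with 3 mutant samples for Microfold) and bars give the mean with its SD. In Microfold cells the liver list was at 561.5 CPM in control and 70.0 CPM in mutant samples.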

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

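The comparisons of single samples with their group and of classes with Tuft cells were planned, and no test in this part was chosen after its result was seen. The share of Muscle cells, mTEC with genes of skeletal muscle, was 0.969%, 0.726% and 1.01% in mutant samples 1, 2 and 3 and 2.77% in mutant sample 4. The gap to the nearest sample was 0.862 of the whole range, which by Dixon's test is larger than expected for 4 samples. It was the 1 outlying value of 76 tested, and chance alone marks about 1 in 20.

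For the list of lipoprotein and lipid absorption genes, the effect of genotype in 2 classes differed from that in Tuft cells before adjustment. The log2 effect minus that in Tuft cells was -0.78 in Aire-adjacent cells and -0.56 in Neuroendocrine cells, each with an exact permutation p of 0.0286 and an adjusted p of 0.143. Of 40 differences between classes tested, 2 had an unadjusted p under 0.05 and 0 an adjusted one.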

How the results depend on the processing

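The filter of 2000 genes and 5%, leaving out Entero-hepato, Tuft or wrongly tagged cells, and leaving out Reg3g were chosen after the data had been seen. Leiden clusters made without gut and liver genes were the planned classes and became an alternative once the authors' classes were seen. The other alternatives were planned. All 39 genes called in all cells kept their direction in every alternative except without Tuft cells, where 38 did, and Anks4b passed in each. The loss of Entero-hepato cells kept its direction and edgeR call wherever the authors' classes were used. The cause of the changes below was not tested, except that a block or a left-out sample takes away degrees of freedom. In all cells 31.3% of simulated 1.5-fold changes were called.

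In all cells, DESeq2 called 35 genes higher and 188 lower. The replicate block gave 6 lower, thinning to 801 cells 0 higher and 19 lower, weighting to 1 mix 6 higher, leaving out Entero-hepato cells 0 higher and 9 lower, and 0 were higher without cells that Scrublet marked or without wrongly tagged cells. Of the 39 genes called, weighting to 1 mix kept 24 among 59 calls, and leaving out Tuft cells kept 23 among 46. Leaving out 1 sample gave 0 to 1 higher and 2 to 31 lower genes. Whether replicate numbers pair the samples was not settled by their expression. Samples with the same number correlated at 0.466, 0.270 and -0.0502, and the second value was the best match of control sample 2. Control sample 3 correlated best with mutant sample 4, at 0.696. These are sums over all cells, so differences in class mix enter too. The block, with 5 of the 39 genes among its 7 calls, thus stays a possible model. For Hnf4g the log2 fold change was -0.47 with the block, -0.50 thinned, -0.19 with weighting, -0.33 without Entero-hepato cells, -0.55 without Tuft cells and -0.53 to -0.47 with 1 sample left out, and each lost the call.

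Some values changed sign. Without Tuft cells Bex4 was at -0.42, Cd74 at 0.012 and Hsp90aa1 at 0.074; with the block Elf3 was at 0.0058, Fos at 0.026 and Krt8 at 0.019; with weighting Klf4 was at -0.016. With 1 sample left out the ranges were -0.30 to 0.11 for Elf3, -0.14 to 0.18 for Klf4, -0.30 to 0.24 for Cd74, -0.36 to 0.14 for H2-Ab1, -0.052 to 0.017 for Hsp90aa1, -0.48 to 0.12 for Fos and -0.12 to 0.060 for Krt8. None of these but Bex4 had passed.

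For lists, 2 passed with an estimated correlation and 2 with fry. Adjusted p with an estimated correlation and with fry was 0.352 and 0.314 for liver, 0.0925 and 0.0943 for lipoprotein and 0.0839 and 0.0879 for microfold markers. Medians changed sign for the interferon response (-0.016 without Tuft cells), thymic epithelium (0.047 with the block), Aire-stage markers (0.037 without Tuft cells), and immature markers (0.0013 without Tuft cells). The direction given by camera turned for thymocyte markers with the block (-0.18) and the interferon response without cells that Scrublet marked (0.0014). Aire-stage markers (-0.058) and myeloid or B markers (-0.13) also turned without Entero-hepato cells, proliferating markers without Tuft cells (-0.020), and ciliated markers with the block (-0.056), without Entero-hepato cells (-0.048) and at 2000 genes and 5% (-0.032). With 1 sample left out, medians ran from -0.30 to 0.20 for MHC class II, -0.048 to 0.080 for interferon response, -0.43 to 0.051 for dissociation stress, -0.15 to 0.060 for thymic epithelium, -0.24 to 0.22 for Aire-stage, -0.40 to 0.23 for proliferating, -0.15 to 0.34 for tuft, -0.13 to 0.23 for ciliated, -0.27 to 0.10 for keratinocyte, -0.34 to 0.014 for ionocyte, -0.38 to 0.22 for thymocyte and -0.30 to 0.14 for myeloid or B markers. Of 405 list values under alternatives, 15 passed camera in the same direction where the reported test had not, as MHC class II did without control sample 1 (-0.30).

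Within classes, DESeq2 called 25 genes in Aire-adjacent, 49 in Aire-expressing, 46 in Keratinocyte, 74 in Neuroendocrine, 25 in Secretory, 1 in TA, 1 in Transitional and 80 in Tuft cells. Without the filter for low counts edgeR called 279 in Aire-adjacent, 164 in Ciliated, 54 in Immature, 326 in Keratinocyte, 602 in Microfold, 419 in Neuroendocrine, 269 in Secretory, 192 in TA, 115 in Transitional and 470 in Tuft cells. The block gave 73 in Microfold, 1 in Secretory and 2 in TA cells. Without cells that Scrublet marked there were 239 in Microfold, 67 in Neuroendocrine, 6 in Secretory and 1 in TA cells. Leiden clusters with gut and liver genes gave 60 in Aire-adjacent, 86 in Microfold and 0 in Secretory cells, and those without gave 55 in Aire-adjacent, 0 in Secretory and 2 in Transitional cells. The clusters named Aire-adjacent held 60.4 and 63.5% such cells and also 79 and 76 Entero-hepato cells, so their genes mix both classes. With 1 sample left out the counts ran from 0 to 9 in Aire-adjacent, 0 to 2 in Immature, 2 to 18 in Keratinocyte, 28 to 95 in Microfold, 10 to 42 in Neuroendocrine, 0 to 6 in Secretory, 0 to 1 in TA, 0 to 2 in Transitional and 5 to 52 in Tuft cells. At a minimum of 20 cells Ciliated, Microfold and TA cells could not be tested, Leiden clusters without gut and liver genes gave no value for TA, and leaving out mutant sample 4 changes nothing for Microfold cells, where it was not used.

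For shares, the exact permutation gave an adjusted p of 0.286 for Entero-hepato cells. Leiden clusters gave 0 shares past the threshold with gut and liver genes, without them, at resolution 0.5 and at resolution 2. The Tuft share ran from -0.11 to 0.29 with 1 sample left out. For the lipoprotein list in Tuft cells, the mean of log2(CPM + 1) gave -0.082 and leaving out 1 sample -0.042 to 0.18. The shares of Entero-hepato, Microfold, Secretory and Tuft cells and the number of shares past the threshold had 80 alternative values. Of these, 74 gave the same verdict, and among those classes Entero-hepato alone had passed. For the lists by class 171 of 175 values kept their sign and stayed without a call, and 4 changed sign. That agreement says little, since no list by class had passed. With 1 sample left out the exact test has too few splits to pass. Shares of other classes changed sign under some alternatives, as the Muscle share did (1.07 without control sample 3, -0.38 without mutant sample 4), and none of them passed.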

Other observations

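The tests of Entero-hepato RNA within classes, of the cluster's other cells, and of splits for the shares, for single lists and for lists within classes were chosen after the results were seen, while the test of barcodes without annotation and the other splits were planned. Some genes fell in several classes. Rhoc fell in Keratinocyte, Microfold, Neuroendocrine and Tuft cells (4 classes), and Anks4b in Microfold, Neuroendocrine and Tuft cells (3 classes). Another 12 genes fell in 2 classes each, among them Vil1, Myo15b, Calml4 and Cdhr5, the last a cadherin that links microvilli, and Lypd8, a secreted protein of the colon surface; these were chosen after their values were seen. All classes came from the same samples, and the overlap itself was not tested.

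Pth, the parathyroid hormone, was at 281, 608, 903 and 23.9 CPM in mutant samples 1, 2, 3 and 4 and at 4.06, 4.22 and 7.83 CPM in control samples, a log2 fold change of 6.32 that did not pass (SE 1.23, edgeR adjusted p = 0.172). DESeq2 gave an adjusted p of 4.38e-07, and without mutant sample 4 edgeR gave 0.0238; over all alternatives the adjusted p ranged from 4.38e-07 to 0.644. Single cells carried most of its counts, 4580 of 6612 UMIs in mutant sample 1, 11521 of 11589 in mutant sample 2 and 11792 of 18465 in mutant sample 3, in cells annotated as Tuft, TA and Tuft. At least 10 UMIs were found in 0, 0 and 3 cells of the control samples and 3, 1, 2 and 7 cells of the mutant samples. Casr, the calcium receptor of parathyroid cells, did not pass (0.20, edgeR adjusted p = 0.554).

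The near absence of Entero-hepato cells may reflect a lost cell type or a change in how such cells were named. In the cluster that held most of them, the other cells did not increase in the mutant samples. The change was -1.676 percentage points (SE 1.15) where a move under another name needed 2.138, which argues against renaming within that cluster. Renaming into a class outside it was not tested. The largest rises, in Tuft (2.78 percentage points) and Secretory cells (1.88), were near that size but did not pass in edgeR. Barcodes without annotation that had a high share of entero-hepato markers reached 2.476% of annotated cells in the highest mutant sample, against 2.75%, 4.48% and 8.55% in control samples. Since 78 to 185 annotated cells of other classes per sample passed the same bound, loss of such cells and their omission from the annotation cannot be told apart by this test. A gene program lost from cells that remain stays open too, because the class is itself defined by genes that Hnf4 may drive.

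Genes lower in other classes could come from Entero-hepato cells or their RNA mixed into those classes in the control samples alone. All 7 samples went through 1 run, so RNA free in the pool would reach cells of both genotypes. Such free RNA would not by itself make a difference between them. The share of admixed Entero-hepato RNA needed for the lower genes was 16.2% in Tuft, 38.8% in Neuroendocrine, 96.4% in Microfold, 20.2% in Keratinocyte and 32.5% in Secretory cells. The abundant entero-hepato markers Reg3g, Apoc3, Apoa4, Lgals4 and Hnf4g allowed 0.208%, 0.366%, 22.8%, 1.77% and 6.50% in the same order. This argues against such admixture as the whole cause in Tuft, Neuroendocrine and Keratinocyte cells, while a part of the change stays open there. In Microfold and Secretory cells the test is weaker, since the markers allowed 11.5 to 37.3% and 0.624 to 10.4% in single control samples. The needed shares rest on genes chosen for their fall in these data, which raises them. The Secretory value rested on 3 genes, of which Lgals4 is itself among the markers, and Aire-adjacent cells had no lower genes for this test. Lgals4 was also among the lower genes of Neuroendocrine cells, and Reg3g and Apoc3 were among those of Microfold cells. The needed and allowed shares were thus not independent there. Hnf4g is a targeted gene made by other classes too, at 221 and 223 CPM in Neuroendocrine cells, so it is a poor tracer of admixture. Whether loss of Hnf4 acted within those cells or through the missing Entero-hepato cells was not tested.

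Other splits of the samples were counted to see how often they gave results as large. For genes in all cells 1 of 35 splits, the real one, gave as many as 39 genes, with at most 2 in another split. The same held in Tuft (1 split, 13 genes, at most 4 elsewhere), Neuroendocrine (1 split, 44, at most 5) and Keratinocyte cells (1 split, 9, at most 1). A share of 1 in 35 is the smallest possible and was not adjusted over the classes tested. These counts thus exceeded those of every other split but do not exclude chance. In Microfold cells 10 splits are too few for a share under 0.05, with 141 genes in the real split and at most 0 in another. Nor can chance be excluded for the 3 genes of Secretory cells (2 splits, at most 3 elsewhere), where another split gave as many. The same holds for the number of lists (30 splits as many as 8, at most 15 elsewhere) and of class shares (4 splits as many as 1, at most 4 elsewhere). For the Entero-hepato share itself, the exact permutation p of 0.0286 means that 1 of 35 splits, the real one, gave a difference in percentage points as large, before adjustment over the classes (adjusted p = 0.286). On the log2 scale of edgeR 2 of 35 splits gave an absolute fold change as large as 5.25. The other, at 5.67, set mutant samples 2, 3 and 4, with 1 such cell, against the rest, with 84, so on that scale chance cannot be excluded by the count of splits. For the gut epithelium list in all cells, 24 of 35 splits gave an unadjusted camera p under 0.05 with the preset correlation, 1 gave one as small, and 2 gave an absolute median as large, the largest elsewhere being 0.79. For the entero-hepato markers those counts were 25, 1 and 2, with 1.20 the largest elsewhere. Within classes, with an estimated correlation, 1 of 35 splits gave a p for the gut epithelium list as small as the real one in Aire-adjacent, Keratinocyte, Neuroendocrine and Tuft cells, and 1 of 10 in Microfold cells. The absolute median was as large in 2, 1, 3, 2 and 1 splits of those classes. In the classes with 0 genes all 35 splits gave as many by definition, with at most 2 in Aire-adjacent, 1 in Aire-expressing, 100 in Ciliated, 20 in Immature, 9 in TA and 11 in Transitional cells. The split with 100 genes in Ciliated cells set control samples 1 and 2 with mutant samples 1 and 2 against the rest. It thus divided replicate numbers 1 and 2 from 3 and 4, and its cause was not tested. Control sample 3 and mutant sample 4 had fewer Tuft cells (31.1 and 36.7%) and more Aire-expressing cells (13.1 and 12.4%) than the others. Mutant sample 3, on the same side of that split, did not stand apart in this way, at 47.0% and 8.47%.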
